A study of Bos taurus with 8 samples.

How the data were processed

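Cumulus cells were separated from oocytes with 0.1% hyaluronidase and pooled, 4 pools for each age, and amplified RNA (15 µg) was labelled and hybridised, per the labels' protocols. Each of the 8 slides held 1 adult and 1 prepubertal pool, and the labels give the dye of each. Per the file headers, the deposited scanner tables hold intensity values for each of 19200 spots and each dye, with the mean and median over the spot's pixels and the local background, its median and its standard deviation kept apart and not subtracted. The deposited scanner tables also give the percent of a spot's pixels that were saturated. The scanner and image software are not given in the sources used here. The authors' table of processed values is in log2 units and holds 1 column per slide. In all 19200 rows it equals, within 0.001, the scanner's log2 median pixel ratio of adult over prepubertal minus a constant for the slide, so its direction and scale are known. The median of each of its columns is 0, and no correction for intensity was made in it. Pixel positions (unit other in the deposited tables) served only to look for rows out of place.

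Each slide is printed in 48 blocks, with 18263 tag elements, 384 blank spots, 241 negative spots, 120 lambda spots, 96 beta-actin spots and 96 GAPDH spots. The columns for gene symbol, gene name and accession hold no entry. The accession inside an element's identifier matched 0 of the 37063 genes of the reference table. The planned tests of 25 gene lists, their alternatives and the planned rule for named genes therefore could not be run. In place of that rule, the 2 elements with the largest change in each direction were taken among those past the threshold with 1 sign in all 4 pairs.

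Some rows are identical between slides in every measurement column. Slides 8 and 9 share 683 such rows, slides 7 and 9 share 181, slides 7 and 8 share 55 and slides 2 and 3 share 35. The scan positions in the rows shared with slides 9 and 2 lie on the grid of those slides and more than 8 pixels off the grid of slides 8, 7 and 3. Of the 55 rows shared by slides 7 and 8, all are off the grid of slide 8 and 53 off that of slide 7. So 685 spots of slide 8, 181 of slide 7 and 35 of slide 3 were left out as copies. Other spots off the grid and rows with repeated or skipped numbers, 7 on slide 7 and 3 on slide 8, were left out too. Spots marked abnormal by the scanner tables, 14 on slide 1 and 403 on slide 6, were also left out. At least 1 copied row affected 772 elements.

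Ratios were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 on the mean over pixels and the background median, and each slide was normalised by global loess fitted on tag elements, with no scaling between slides. The background correction, normalisation, filter, pairing rule and test were fixed before the data were examined. The mean over pixels as the signal, the leaving out of copied and misplaced rows and the minimum of 3 pairs were chosen after the files had been looked at. Elements were kept where the foreground median exceeded the background median by 2 background SDs in at least 1 dye on at least 4 of the 8 slides, which 11697 elements did. The slides were combined into 4 dye-swap pairs, and the average of a pair was 1 replicate, since 4 pools per age on 8 slides with a dye swap imply that each pool was hybridised to 2 slides. Elements with at least 3 complete pairs were tested, 11110 with 4 pairs and 432 with 3, by lmFit and eBayes with an intercept only and Benjamini-Hochberg adjustment. The prior degrees of freedom were 6.79.

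The labels and headers do not say which slides hold the same pools. By a rule fixed beforehand, partners would be taken from the matching with the highest summed correlation of slide deviations (taken here from the mean of the slide's own orientation) if every pair correlated over 0.1. None of the 24 matchings met this, so slides were paired in number order, 1 with 6, 2 with 7, 3 with 8 and 4 with 9, whose correlations were 0.252, -0.0606, 0.0741 and -0.106. The numbers of calls of the 24 matchings were seen together with these correlations. The pairing is an assumption, and p-values measure the spread between these 4 pairs. The plate names in the file headers set slides 1 and 6 apart from the other 6 slides. As a batch term, this name was added to a fit of the 8 slides. Within the batch of slides 1 and 6 there is only 1 pair and no test, and the batch of the other slides is the fit without that pair, which called 923 elements.

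GAPDH and beta-actin were summarised as the median over control spots on each slide and tested over pairs by an exact two-sided sign-flip test. The bound for an element with 1 age not above background on any slide used signals for each dye after loess and Aquantile scaling. The dye effect was the dye term of a fit of the 8 slides. The fit was tested on simulated data for the comparison of the ages, with 11542 elements and 200 changed elements in each of 10 runs. It called 98.6% of 1.5-fold changes and 99.9% of 2-fold changes, and 6.10% of its calls were false. No smaller change was simulated, so these shares do not describe smaller changes, and the median real call was 1.29-fold. Doubling the prepubertal signal of 100 elements in the scanner values moved their median log2 ratio by 0.99, and doubling the adult signal of 100 others moved it by -0.95.

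The alternatives were no background correction, plain subtraction, print-tip loess, median centring, scale and Aquantile normalisation between slides, other filters, abnormal spots kept, other models of the 8 slides, single orientations, the 24 matchings, array weights, a trended and robust eBayes, each pair left out, the authors' values and other thresholds. Number order of the labels, planned as an alternative pairing, became the main pairing. Added after seeing the data were all rows used as deposited, the median over pixels, a filter on both dyes, centring of each source plate and leaving out spots with saturated pixels.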

Results

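Transcript abundance was measured in cumulus cells, the somatic cells that surround the oocyte in the follicle, from adult and prepubertal cattle. Each age was represented by 4 pools, each holding the cumulus cells of 18 to 20 oocytes from follicles of 3 to 7 mm. The pools were compared on 8 two-colour cDNA slides that carried 18263 elements printed from bovine expressed sequence tags. On the 4 slides numbered 1 to 4 the adult RNA was labelled with Cy3 and the prepubertal RNA with Cy5, and on the 4 slides numbered 6 to 9 the dyes were swapped. Between 49.1% and 68.0% of the elements were above the local background in at least 1 dye on a slide. The number of slides, and the 4 pools per age behind them, limit the precision of every value. All ratios are given as log2 of prepubertal over adult, and a positive value means more RNA in prepubertal cumulus cells.

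The comparison asks which transcripts differ in abundance between cumulus cells of adult animals and those of prepubertal animals, whose oocytes the study uses as a model of low quality. Of 11542 elements tested, 889 were higher and 768 lower in prepubertal cells, 1657 in all or 14.4% (limma on 4 dye-swap pairs, Benjamini-Hochberg adjusted p under 0.05). The median change among these elements was 1.29-fold, with quartiles of 1.24 and 1.40, against a median standard error of 0.080 on the log2 scale over the tested elements. Elements lower in prepubertal cells outnumbered those higher once a minimum size was set. At 1.5-fold or more, 96 elements were higher and 169 lower, and at 2-fold or more 19 were higher and 64 lower. Detection was unequal: of the 1657 elements, 713 had adult RNA above background on all 8 slides and 230 had prepubertal RNA above it. Slide 4 limits the second count, since 10.5% of its elements were above background in the dye of its prepubertal RNA. On the other slides that share was 30.3% to 65.4%, against 39.8% to 68.0% for adult RNA over the 8 slides. Whether unequal detection shaped the counts by size was not tested. An unadjusted p under 0.05 was reached by 3652 elements, where 577.1 would be reached by chance. The change had the same sign in all 4 pairs for 1592 of the 1612 called elements with 4 pairs, and in all 3 pairs for the 45 with 3. The call itself, on the mean of these pairs against their spread, nearly fixes these signs, so they are no separate evidence. On all 8 slides the change had the same sign for 760 of the 1612, 349 higher and 411 lower in prepubertal cells. Selection on the mean of the pairs favours this too. Over all tested elements, 8.71% kept 1 sign on the 8 slides, which share pools and dye effects and so are not independent. RNA of 1 age was above background on no slide for 14 of the 1657 elements, for prepubertal RNA in 13 and for adult RNA in 1, and 1 of the 19 and 2 of the 64 elements changed by at least 2-fold are among them.

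**Figure D1:**
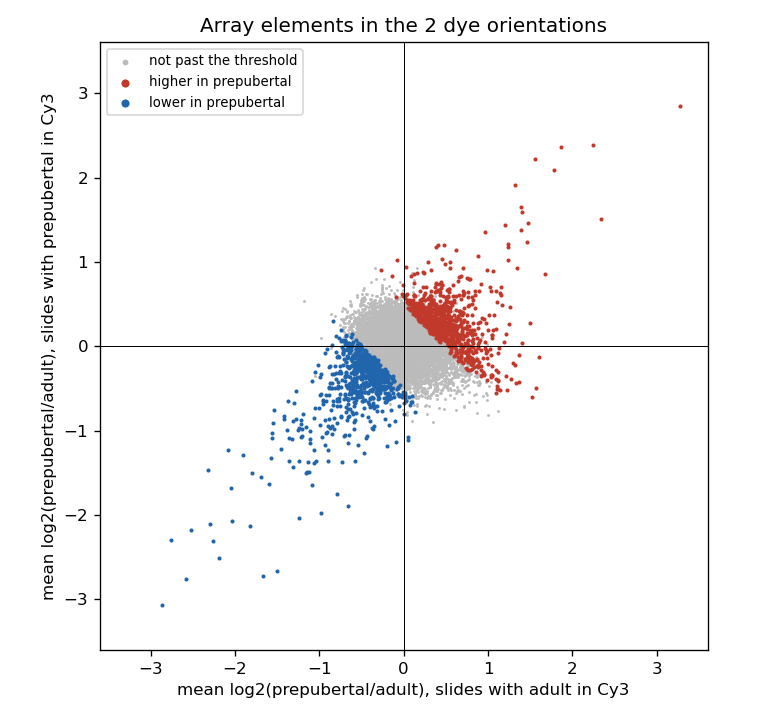
Each point is 1 of the tested array elements, with its mean log2(prepubertal/adult) over the slides with adult RNA in Cy3 on the horizontal axis and over the slides with prepubertal RNA in Cy3 on the vertical axis. The 889 elements higher in prepubertal cells (red) lie towards the upper right and the 768 lower (blue) towards the lower left, while the remaining elements (grey) surround 0.

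The count depended on the choice of signal and was lower with any pair of slides left out. It was 863 without background correction, 832 (337 higher, 495 lower) with the median over a spot's pixels and 2597 (812 higher, 1785 lower) with the authors' centred ratios. It was 1009 for elements above background on all 8 slides and 1092 for elements above background in both dyes on at least 4 slides. Leaving out the pair of slides 1 and 6 gave 923 elements and leaving out slides 2 and 7 gave 750. Leaving out slides 3 and 8 gave 1480, and leaving out slides 4 and 9 gave 630. Each of these fits had fewer pairs, which alone can lower the number of calls.

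The files give an identifier for each element but do not pair it with a gene, so the elements with the largest changes in each direction are given by identifier. NBFGC_BG693208 was higher in prepubertal cells, with a log2 ratio of 3.06 ± 0.43 (SD, n = 4 pairs) and a limma adjusted p of 7.95e-07. Its prepubertal signal was above background on 6 slides and its adult signal on 1, so the size of the ratio rests on the background correction. NBFGC_BG688948 was also higher in prepubertal cells, with a limma adjusted p of 2.75e-05. Its adult signal was not above background on any slide, so the size of its log2 ratio, 2.32, rests on the background correction. A value set against a floor, called the bound, is given beside that ratio. Under the main background correction and the mean over pixels the bound was 4.87-fold, and it was lower under the other signals given below. The bound sets the mean prepubertal signal against the lowest signal above background on each slide, or the adult signal of NBFGC_BG688948 itself where that was higher. This floor averaged 11.01 on the log2 scale, against 10.98 for the adult signal itself. The bound of 4.87-fold is therefore nearly the fitted ratio of 4.99-fold and is not a cautious lower limit. The prepubertal signal of NBFGC_BG688948 was above background on 4 slides. NBFGC_BF599497 was 7.82-fold lower in prepubertal cells, with a log2 ratio of -2.97 ± 0.30 (SD, n = 4 pairs) and a limma adjusted p of 3.23e-07. NBFGC_BE590193 was 6.38-fold lower, with a log2 ratio of -2.67 ± 0.21 (SD, n = 4 pairs) and the same adjusted p of 3.23e-07. The adult signal of both was above background on 8 slides and the prepubertal signal on 4. Each of the 4 elements had the same sign on all 8 slides. With spots that held saturated pixels left out, only NBFGC_BE590193 could still be tested, at a log2 ratio of -2.64. That value equals the one without the pair of slides 3 and 8, so this element too lost a pair. The ratios of all 4 elements therefore rest in part on such spots. The size of the changes depended on background correction: without it the log2 ratios were 1.18 for NBFGC_BG693208, -1.71 for NBFGC_BF599497 and -1.35 for NBFGC_BE590193, all still past the threshold. The bound for NBFGC_BG688948 was 2.31-fold without background correction, where the floor was again nearly the adult signal itself. With the median over pixels it was 1.49-fold.

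GAPDH and beta-actin are the genes named on the slides, both through control spots printed 96 times each. GAPDH, a glycolytic enzyme often used as a reference transcript, had a mean log2 ratio of -0.16 ± 0.31 (SD, n = 4 pairs) and no difference between the ages was detected (exact two-sided sign-flip test, p = 0.375). Beta-actin, a cytoskeletal protein, had a mean log2 ratio of -0.22 ± 0.31 (SD, n = 4 pairs; exact two-sided sign-flip test, p = 0.25). With 4 pairs the smallest p this test can give is 0.125, so neither gene could have passed 0.05. The slide values of GAPDH ranged from -1.13 on slide 3 to 0.52 on slide 2, and those of beta-actin from -0.75 on slide 6 to 0.32 on slide 7. The mean of GAPDH was -0.28 without slides 1 and 6 and -0.03 without slides 3 and 8, and that of beta-actin was -0.11 without slides 1 and 6 and -0.36 without slides 2 and 7. Many of these spots held saturated pixels, 93.8% of the GAPDH spots on slide 3 and 92.7% of the beta-actin spots on slide 1.

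**Figure D2:**
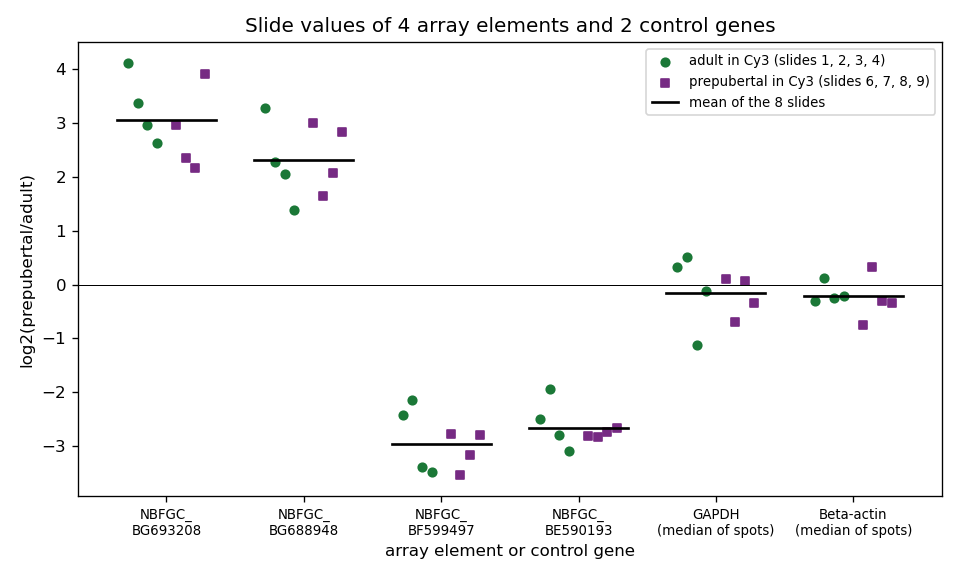
The vertical axis gives log2(prepubertal/adult) on each slide, with circles for slides with adult RNA in Cy3, squares for slides with prepubertal RNA in Cy3 and a line at the mean of the 8 slides. All slide values of the 4 array elements lie on 1 side of 0, while GAPDH (from -1.13 to 0.52) and beta-actin (from -0.75 to 0.32) lie on both; the adult signal of NBFGC_BG688948 was above background on no slide.

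The dye swap shows how far the ratio of an element depended on which age carried which dye. Across 11697 elements, the mean log2 ratios of the 2 dye orientations had a Pearson correlation of 0.184 and a Spearman correlation of -0.0109, and 48.3% of the elements had the same sign in both (elements are not independent replicates). Slides of the same orientation correlated more closely, at 0.403 to 0.688 for adult RNA in Cy3 and 0.477 to 0.778 for prepubertal RNA in Cy3, than slides of opposite orientation, at -0.0195 to 0.323. A dye effect of the single element passed the threshold for 2466 of 11542 elements (limma, Benjamini-Hochberg adjusted p under 0.05), and 381 of these also differed between the ages. The dye effect had an SD of 0.20 across elements and the age effect an SD of 0.24, both on the log2 scale. In the median element the order was reversed, with an absolute dye effect of 0.129 and an absolute age effect of 0.125. The dye-effect count was 837 with the median over pixels and 4238 with median centring in place of loess. The Pearson correlation of the orientations was 0.0226 with median centring and 0.264 with each source plate centred.

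**Figure D3:**
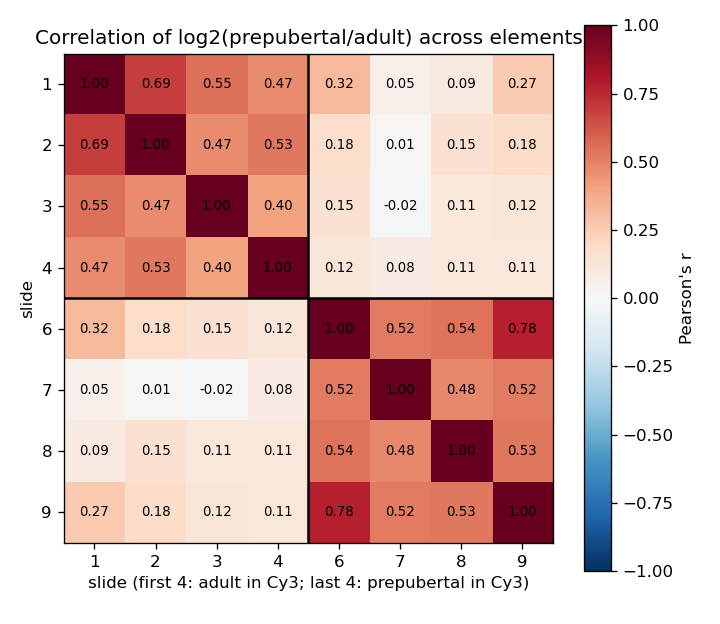
Pearson's r of log2(prepubertal/adult) across elements is given for each pair of the 8 slides, with lines between the 4 slides that carry adult RNA in Cy3 and the 4 that carry prepubertal RNA in Cy3. Correlations within an orientation range from 0.403 to 0.778 and those across orientations from -0.0195 to 0.323.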

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

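The tests of this part were set out before their results were seen, except the shares of the log2 change left after a correction; centring of source plates and the signs in left-out pairs were added after the data had been seen. A slide was singled out where its gap to the nearest of the 4 slides of its orientation was a larger part of their range than Dixon's critical value for 4 values allows. Over 30 such groups, chance alone singles out about 1 in 20. Slide 4 had a median Cy5 background of 9919, against 4840 to 5132 on the other slides with adult RNA in Cy3. Its median Cy5 foreground was 11792, against 7057 to 7703, and 10.5% of its elements were above background in Cy5, the dye of its prepubertal RNA. Slide 9 had saturated pixels in 4.56% of its elements, against 3.14% to 3.37% on the other slides with prepubertal RNA in Cy3.

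The change between the ages differed between the 2 dye orientations for 2466 elements, by the dye term of the limma fit of 8 slides. For the 1657 elements called between the ages, differences between printed blocks or between source plates are argued against as the whole cause. Print-tip loess gave 1557 calls, of which 1221 were among the 1657 with the same sign. It left a median of 89.8% of the log2 change of the 1657 elements (lower quartile 77.0%). Centring each source plate gave 1266 calls, of which 1124 were among the 1657 with the same sign. It left a median of 91.5% (lower quartile 80.9%). Effects of position within a block were not tested. A part of block or plate effects in single calls stays open, since 73.7% and 67.8% of the calls were kept. The median fold of the calls lost went from 1.23 to 1.15 under print-tip loess and from 1.24 to 1.18 under plate centring. Their median standard errors were 0.077 and 0.072, and 0.080 and 0.077, before and after. Dye effects on single elements, which give the 2 slides of a pair opposite signs and cancel in its mean where equal in size, are argued against as the whole cause: of the elements called without a pair, 60.6% (slides 3 and 8) to 82.1% (slides 4 and 9) had the called sign on both slides of the pair left out, where 2 random signs give 25%. Whether unequal dye effects left a part in single calls was not decided: the age change and the mean dye effect of called elements had a Spearman correlation of 0.273, between the bounds of 0.2 and 0.5. Of the 8 sign flips of the 4 pairs, 1, the real one, gave 1657 elements and the highest of the others gave 0, but 8 flips are too few for a share under 0.05. A difference between the cells of the 2 ages stays among the open explanations.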

How the results depend on the processing

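The median over pixels, the filter on both dyes, plate centring, all rows as deposited and leaving out saturated spots were chosen after seeing the data. The count of elements that differed between the ages, 1657, stayed within 1.5 times under 20 of 28 alternatives, at 1141 to 2256. These 20 include Aquantile scaling. They also include the 2 single orientations, where age and dye cannot be told apart. A similar count need not hold the same elements, and 37.2% to 100% of the 1657 calls were kept over the 28 alternatives. The count moved to 863 without background correction, 832 (40.5% higher, against 53.7%) with the median over pixels, 2597 (31.3% higher) with the authors' values, 1009 above background on all 8 slides and 1092 above background in both dyes. The last 2 test fewer elements; the cause of the others was not tested. Leaving out a pair gave 630 (slides 4 and 9), 750 (slides 2 and 7), 923 (slides 1 and 6) or 1480 (slides 3 and 8). Other thresholds gave 3652 (unadjusted p), 2648 (adjusted p under 0.1) and 265 (1.5-fold). With no filter, 710 of the 1657 remained. The 24 pairings of slides gave 1335 to 2160, and 1100 elements were called with 1 sign in all of them. Another pairing cannot change the mean of an element with values on all 8 slides. For such elements the shared sign was fixed in advance, and only the spread between pairs was tried. Single orientations gave 1967 and 2256 elements, of which 957 and 780 were among the 1657 with the same sign. Aquantile scaling leaves ratios unchanged, so it tests nothing. The plate name as a block gave 1696.

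The dye-effect count, 2466, moved to 4238 with median centring, 4327 with the authors' values, 837 with the median over pixels, 1559 above background on all 8 slides, 1595 in both dyes and 1563 with plates centred; the cause was not tested. The correlation of the orientations was 0.0226 with median centring. The 4 printed elements passed the threshold with the same sign in every alternative that tested them, which their choice as the largest changes in these data favours. NBFGC_BG693208 and NBFGC_BG688948 were tested under 25 of the 28 alternatives, NBFGC_BF599497 under 27 and NBFGC_BE590193 under 28. Several of these alternatives cannot change a ratio. No alternative run for them turned the sign of the mean of GAPDH or beta-actin, but other pairings cannot change that mean. GAPDH was higher in prepubertal cells on 4 slides and lower on 4, and beta-actin higher on 2 and lower on 6. No direction was therefore shown for either gene. Gene lists were not run. Signal over background limits the prepubertal RNA most on slide 4.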

Other observations

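The tests for a local defect, for mislabelled dyes and for a difference between pools were chosen only after the GAPDH values were seen. GAPDH had a median log2 ratio of -1.13 on slide 3, below the -0.12 to 0.52 of the other 3 slides with adult RNA in Cy3. A local defect is argued against by 97.9% of its spots, which lie in all 48 printed blocks, being below the lowest median of those slides. Mislabelled dyes are argued against by slide 3 correlating at 0.403 or more with each of the other 3 slides. Saturation stays open: 5 spots had no saturated pixels, and their median was 0.55 below that lowest median, with an SD of 1.05 between them. A difference between the pools may also remain, since the nearest slide of the other orientation differed from slide 3 by 0.43 in GAPDH and a dye effect on GAPDH could hide a match.

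Among the 25% of tested elements with the dimmest signal, 62.4% of the calls were higher in prepubertal cells, against 49.6% among the brightest 25%. The printed block of an element accounted for 6.73% of the variance of the age change, against 0.408% when shuffled, and its source plate for 6.33%, against 0.427%. With all rows as deposited, 1709 elements were called, of which 96.5% were also called without the copied rows. Only 4.10% of those calls, 70 elements, have a copied row, so that share was nearly fixed and decides nothing about the copies. Of the 70, 29 were also called without the copies, 23 were tested and not called, and 18 were no longer tested because too few pairs were left.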
